A study of Homo sapiens with 4 samples.

How the data were processed

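The data are chromatin immunoprecipitation sequencing (ChIP-seq) of the transcription factor BACH1 in 2 human airway epithelial cell lines, with 2 replicates per line and 4 samples in all. Per the labels' protocols, nuclei were lysed, the chromatin was sheared by sonication and precipitated with a rabbit antibody against BACH1, fragments were size-selected, and libraries were sequenced on an Illumina instrument. Each line is represented by 1 peak list. Per the labels, each list came from both replicates through the irreproducible discovery rate (IDR), which keeps peaks that rank alike in a pair of replicates. The build was hg19, per the submitters' processing notes and, for 16HBE14o-, per the file headers. The aligner, the peak caller, its version, the filters and any control library are not given in the sources used here, and the read depth behind the lists is unknown.

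The columns of the lists differ between the lines. For Calu3 the authors deposited a fold enrichment per peak (read as such from the format and the values, since the caller is not named), the −log10 p and −log10 q of each peak, and a browser score that is about 10 times the −log10 p. For 16HBE14o- the authors deposited a peak signal on another, unstated scale, a browser score from 540 to 1000, and a further score from −0.14 to 3.34 in the place of the q column. Because that score goes below 0, which the −log10 of a probability cannot, it was not read as a −log10 q. The Calu3 peaks were 153 to 2234 bp wide (median 235), whereas 98.4% of the 16HBE14o- rows were exactly 240 bp wide. The lists may thus have been made with different callers or thresholds, which the sources used here do not settle. Signal values were therefore used only to rank peaks within their own list and never to compare the lines. Because each list pools its replicates, no measure of replicate spread enters any comparison between the lines. Intervals and p-values below describe the regions of these lists, which are not biological replicates and lie partly in groups along the genome, so p-values over regions are too small.

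Rows that overlapped were merged into unique regions, each with the highest signal and the summit of its strongest row. A region was shared when it met a region of the other list by at least 1 bp. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only. The overlap was compared with 1000 circular shifts of one list, chromosome by chromosome, within the span that the 2 lists cover; the smallest p this allows is 0.001. Within-list percentiles of signal of shared and unshared regions were compared by a two-sided permutation test of the difference of medians with 100000 resamples, whose smallest p is 1e-05. The share of regions on each of 23 chromosomes (1 to 22 and X) was compared between the lists by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 23. The few Calu3 regions on chromosome Y were not compared but stayed in the total of their list. Windows of 100 kb with 3 or more regions were counted against 1000 uniform placements of the regions within each chromosome's span. Coordinates are 1-based and on hg19.

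The regions named are, by a rule fixed before the data were examined, the 10 with the highest signal in each list, the 10 shared regions with the lowest sum of ranks, and the 5 windows of 100 kb with most regions per list. Further regions and stretches were chosen after seeing the data, as stated where they are given. The analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. They were tested on simulated data: a planted sharing of 40.0% of the 3393 regions of the 16HBE14o- list was recovered as 40.1% on average, 4 of 100 unrelated list pairs (50 shifts each) had an overlap p below 0.05, a planted shift of 20 percentile points over 3000 values was recovered as 20.1, and a doubled share of chromosome 3 was called in 50 of 50 draws, against 1 of 50 draws with a call when no chromosome differed. The simulated regions were placed or drawn independently of one another, whereas the regions of the lists lie partly in groups. The simulated rates of false calls therefore do not measure how often grouped regions give a call.

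Alternatives changed the overlap rule, the list length, the peak width, the shift, the merging of rows, the ranking column and the window size. The planned annotation of peaks, the enrichment of 14 gene lists and 12 sequence motifs, and the survey of the CFTR locus needed a genome or gene annotation of the hg19 build and were not analysed here, so regions are given by position and not assigned to genes.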

Results

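BACH1 is a basic leucine zipper transcription factor that binds haem, pairs with small MAF proteins and represses genes of the oxidative stress response. The study asked whether it also takes part in the regulation of CFTR, the gene of the chloride channel that is defective in cystic fibrosis. BACH1-bound regions were mapped in Calu3, a human lung adenocarcinoma line, and in 16HBE14o-, an immortalised human bronchial epithelial line. Each line contributed 2 ChIP-seq replicates, combined by the authors into 1 list of reproducible peaks. The comparisons that the design allows are therefore between 2 lists, with no replicate check on any difference between the lines. The peaks were not assigned to genes here.

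BACH1 occupied 10246 regions in the Calu3 list and 3393 in the 16HBE14o- list, a ratio of 3.02. The lists may have been made with different peak callers or thresholds, since their widths and columns differ, so the ratio does not compare the amount of binding. The 16HBE14o- list held 3415 rows, of which 44 overlapped a neighbour and were merged into 22 regions, while no Calu3 rows overlapped. The Calu3 regions covered 2.69 Mb and the 16HBE14o- regions 0.812 Mb. In Calu3 the median fold enrichment was 4.13 (interquartile range 3.17 to 6.23) and the maximum 53.0. In 16HBE14o- the median peak signal, on its own scale, was 30.1 (interquartile range 24.8 to 41.8) and the maximum 366. Of the Calu3 regions, 2731 (26.7%, 95% interval 25.8 to 27.5) had a deposited q of 0.05 or more, and 784 of these had a −log10 q of 0. The other 7515 regions had a q under 0.05.

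Of the 500 strongest 16HBE14o- regions, 453 (90.6%, 95% interval 87.7 to 93.0) were also bound in the Calu3 list, and of the 500 strongest Calu3 regions 323 (64.6%, 95% interval 60.2 to 68.8) were bound in that of 16HBE14o-. Over the whole lists, 1579 of the 3393 regions of 16HBE14o- (46.5%, 95% interval 44.8 to 48.2) met a Calu3 region, and 1572 of the 10246 Calu3 regions (15.3%, 95% interval 14.6 to 16.1) met one of 16HBE14o-. Circular shifts of the lists gave on average 6.36 shared 16HBE14o- regions and at most 15, so that the observed number was 248 times the shifted mean (one-sided permutation p by shifting = 0.001, the smallest that 1000 shifts can give). Moving the regions by only 10 to 100 kb, which keeps them in the same part of the chromosome, left a ratio of 122. Neither kind of shift takes account of genes or open chromatin. The ratios therefore do not show how much of the overlap is particular to BACH1. The percentages depended on the length of the lists. With Calu3 restricted to its 3393 strongest regions, 31.1% of the 16HBE14o- regions and 30.9% of the Calu3 regions were shared. The shared regions were placed alike, with a median distance between the paired summits of 18 bp (interquartile range 9.0 to 36.0), and 1383 of the 1579 pairs (87.6%) had summits within 50 bp.

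Sharing followed the strength of the site in both lines. In 16HBE14o-, 93.2% (95% interval 90.02 to 95.7) of the regions in the strongest decile were shared, against 15.0% (95% interval 11.4 to 19.3) in the weakest. In Calu3 the strongest decile reached 53.5% (95% interval 50.4 to 56.6) and the weakest 4.49% (95% interval 3.31 to 5.95). The median within-list percentile of signal was 72.0 for shared and 33.8 for unshared 16HBE14o- regions, and 82.3 for shared and 45.1 for unshared Calu3 regions. The differences, 38.2 and 37.2 percentile points, each had a permutation p of 1e-05, the smallest that 100000 resamples can give. Among shared regions the ranks in the lists were correlated across regions (Spearman's rho = 0.53 over 1579 pairs, permutation p = 1e-05). Regions are not independent replicates, and no correlation across samples could be computed. Requiring a reciprocal overlap of 50% lowered the share in the strongest decile to 54.3% in 16HBE14o- and 34.5% in Calu3. In 16HBE14o- the counterparts of all 132 regions lost were over 2 times as wide, which rules out such an overlap. The widths of the Calu3 regions lost were not examined. With summits within 100 bp the shares were 91.7% in 16HBE14o- and 53.3% in Calu3.

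**Figure D1:**
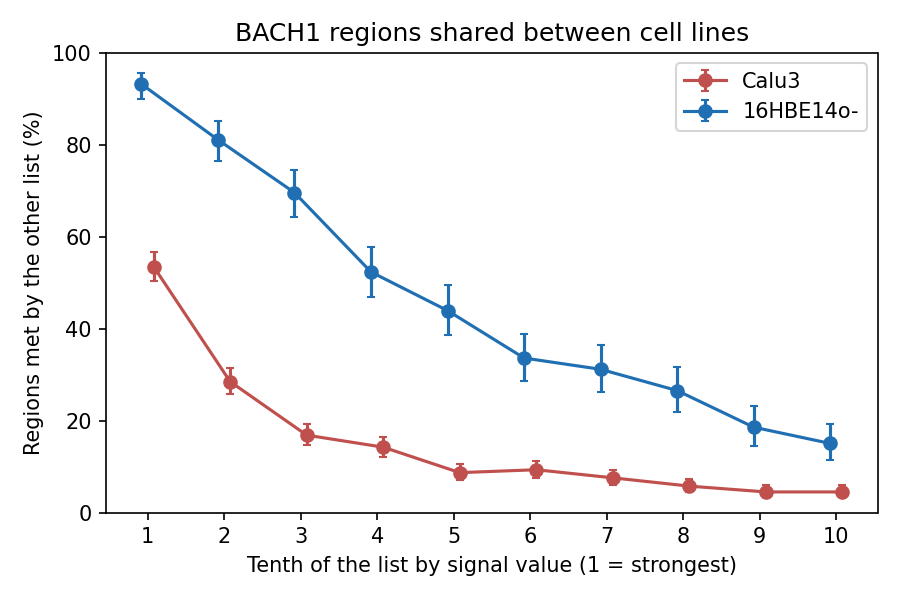
Share of regions met by the other list (y axis, percent) in each decile of a list ranked by the authors' signal value (x axis, 1 is the strongest). Points are Calu3 (red) and 16HBE14o- (blue), bars are 95% exact binomial intervals. The share falls from 93.2% to 15.0% in 16HBE14o- and from 53.5% to 4.49% in Calu3.

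The 10 strongest regions of each line were all bound in the other line, and 2 of them were among the 10 strongest of both. The shared region with the best combined rank lay on chromosome 11 from 66659698 to 66659896 in 16HBE14o- and ranked 3 in both lists, with a signal of 311 in 16HBE14o- and a fold enrichment of 52.1 in Calu3. It was followed by chromosome 1 from 9779261 to 9779418, which ranked 6 in 16HBE14o- and 1 in Calu3, where it had a fold enrichment of 53.0. The pair of regions that ranked 1 and 2 in 16HBE14o- lay side by side on chromosome 22, at 35772972 to 35773205 and 35767950 to 35768195, with signals of 366 and 333. Their counterparts ranked 24 and 12 in Calu3, with fold enrichments of 33.9 and 42.4. The summits of this pair were 5024 bp apart in 16HBE14o- and 5023 bp apart in Calu3.

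Among the remaining regions with the lowest rank sums, the region on chromosome 1 from 204616759 to 204616914 ranked 11 in 16HBE14o- and 4 in Calu3. On chromosome 8, the region from 131012236 to 131012379 ranked 7 and 13, and on chromosome 16 the region from 1429013 to 1429161 ranked 17 and 5, in the same order of lines. The set was completed by chromosome 11 from 61739422 to 61739591 (ranks 15 and 10), chromosome 3 from 53304213 to 53304347 (ranks 23 and 2) and chromosome 7 from 100743494 to 100743665 (ranks 5 and 21). Over these 10 regions the summits of the lines differed by 0 to 21 bp.

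**Figure D2:**
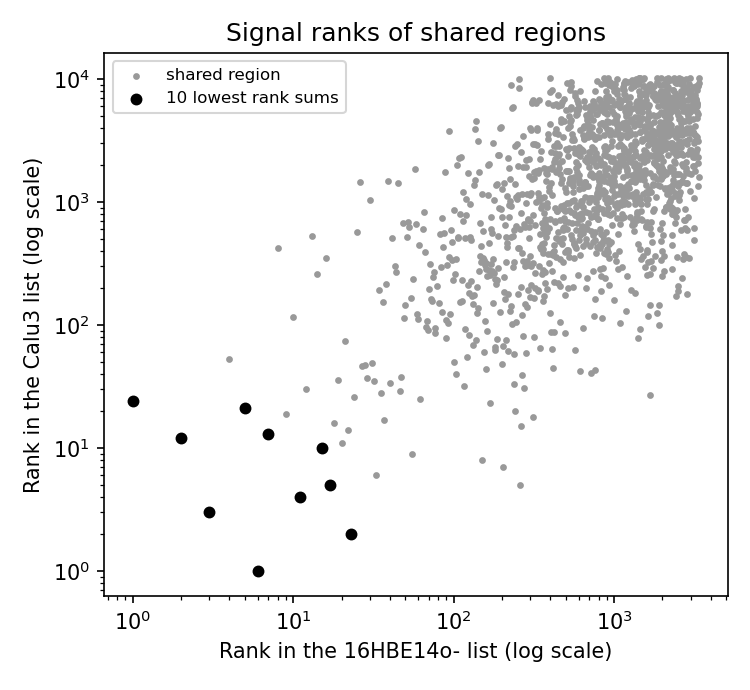
Rank in the Calu3 list (y axis, log scale) against rank in the 16HBE14o- list (x axis, log scale) for the 1579 pairs of shared regions, where 1 is the strongest. Grey points are all pairs and black points the 10 with the lowest rank sums, the first of which ranks 3 in both lists.

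The other strongest sites of Calu3 were chromosome 17 from 78228392 to 78229002, chromosome 3 from 10018546 to 10019136, chromosome 11 from 9385472 to 9386302 and chromosome 5 from 140098172 to 140098711. They ranked 6, 7, 8 and 9 in Calu3, with fold enrichments of 48.3, 48.0, 46.0 and 45.4, and ranked 33, 203, 151 and 55 in 16HBE14o-. In 16HBE14o- the remaining top regions were chromosome 6 from 3002151 to 3002331 (rank 4, signal 277), chromosome 14 from 103603454 to 103603582 (rank 8, signal 235), chromosome 4 from 8305441 to 8305586 (rank 9, signal 232) and chromosome 6 from 17908036 to 17908166 (rank 10, signal 229). They ranked 53, 425, 19 and 116 in Calu3. Ranks from lists of different lengths and scales cannot show whether binding differed between the lines.

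The BACH1 regions of the 2 lists were distributed differently over the chromosomes. The comparison cannot separate binding from copy number or from the processing of the lists. Chromosome 3 held 13.5% (95% interval 12.9 to 14.2) of the Calu3 regions and 5.89% (95% interval 5.13 to 6.74) of those of 16HBE14o-. Chromosome 20 held 4.05% (95% interval 3.68 to 4.45) of the Calu3 regions and 10.3% (95% interval 9.26 to 11.3) of those of 16HBE14o-. Both differences had an adjusted p of 1.66e-36 by Fisher's exact test. Chromosome 14 held 2.59% in Calu3 and 6.34% in 16HBE14o- (adjusted p = 3.71e-21, Fisher's exact test), and chromosome 11 held 3.83% and 6.40% (adjusted p = 9.46e-09, Fisher's exact test). Of the 23 chromosomes, 16 differed at an adjusted p under 0.05. The share was higher in Calu3 for 8 of them (3, 5, 7, 8, 10, 12, 18 and X) and higher in 16HBE14o- for the other 8 (6, 11, 14, 15, 16, 20, 21 and 22). In the upper 50% of each list 8 of the 16 calls were kept, and chromosomes 5, 6, 7, 8, 12, 15, 18 and 21 lost theirs (adjusted p from 0.067 to 0.75, Fisher's exact test). The difference, Calu3 minus 16HBE14o-, went from 1.23 to 1.38 percentage points on chromosome 12, but from 2.09 to 1.12 on chromosome 5, from 1.30 to 0.238 on chromosome 7, from 1.83 to 0.750 on chromosome 8 and from 1.30 to 0.472 on chromosome 18. It went from −2.12 to −1.01 on chromosome 6, from −0.760 to −0.586 on chromosome 15 and from −0.801 to −0.400 on chromosome 21. Under a pair of settings chosen after seeing the data, 14 calls were kept without Calu3 regions of q 0.05 or more and 11 without the windows of 100 kb that held 3 or more regions. The former ended the calls of chromosomes 7 and 15, whose differences kept their direction. They went from 1.30 to 0.919 points (adjusted p = 0.068, Fisher's exact test) and from −0.760 to −0.535 (adjusted p = 0.12, Fisher's exact test). Leaving out the windows of 3 or more regions ended the calls of chromosomes 7, 8, 11, 15 and 18, with adjusted p from 0.080 to 0.56 (Fisher's exact test). The difference went from 1.30 to 0.416 points on chromosome 7, from 1.83 to 0.949 on chromosome 8 and from 1.30 to 0.485 on chromosome 18. On chromosome 15 it changed little, from −0.760 to −0.686 points. Chromosome 11 then held 4.05% in Calu3 and 4.61% in 16HBE14o- (adjusted p = 0.28, against 2.17e-06 to 0.28 over its 3 alternatives, Fisher's exact test). Chromosome 4, at 3.97% in Calu3 and 3.21% in 16HBE14o-, was not called over the whole lists (adjusted p = 0.065, Fisher's exact test) but was higher in Calu3 under all 3 alternatives (adjusted p from 0.00088 to 0.034, Fisher's exact test). The calls of chromosomes 3, 10, 14, 16, 20, 22 and X were kept under all 3. Without the windows of 3 or more regions, the differences on chromosomes 3, 14 and 20 were smaller. They went from 7.65 to 5.02 points, from −3.75 to −1.91 and from −6.21 to −3.92, respectively. The differences on chromosomes 10, 16 and 22 changed less, and that on X grew from 0.780 to 1.27 points.

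On chromosome 3 the Calu3 share was the higher one both below 80 Mb and from 90 Mb onwards. From 90 Mb the chromosome held 1039 Calu3 regions (10.1% of the list, 95% interval 9.56 to 10.7) and 101 regions of 16HBE14o- (2.98%, 95% interval 2.43 to 3.61). From 0 to 80 Mb it held 337 Calu3 regions (3.29%, 95% interval 2.95 to 3.65) and 44 of 16HBE14o- (1.30%, 95% interval 0.944 to 1.74). Between 80 and 90 Mb the order was the other way round, with 12 Calu3 regions and 55 of 16HBE14o-. On chromosome 20, the part from 30 Mb onwards held 318 regions of 16HBE14o- (9.37%, 95% interval 8.41 to 10.4) and 344 Calu3 regions (3.36%, 95% interval 3.02 to 3.72). Below 30 Mb it held 0.884% (95% interval 0.597 to 1.26) and 0.693% (95% interval 0.542 to 0.873). These dividing positions were chosen after the counts per chromosome were seen.

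**Figure D3:**
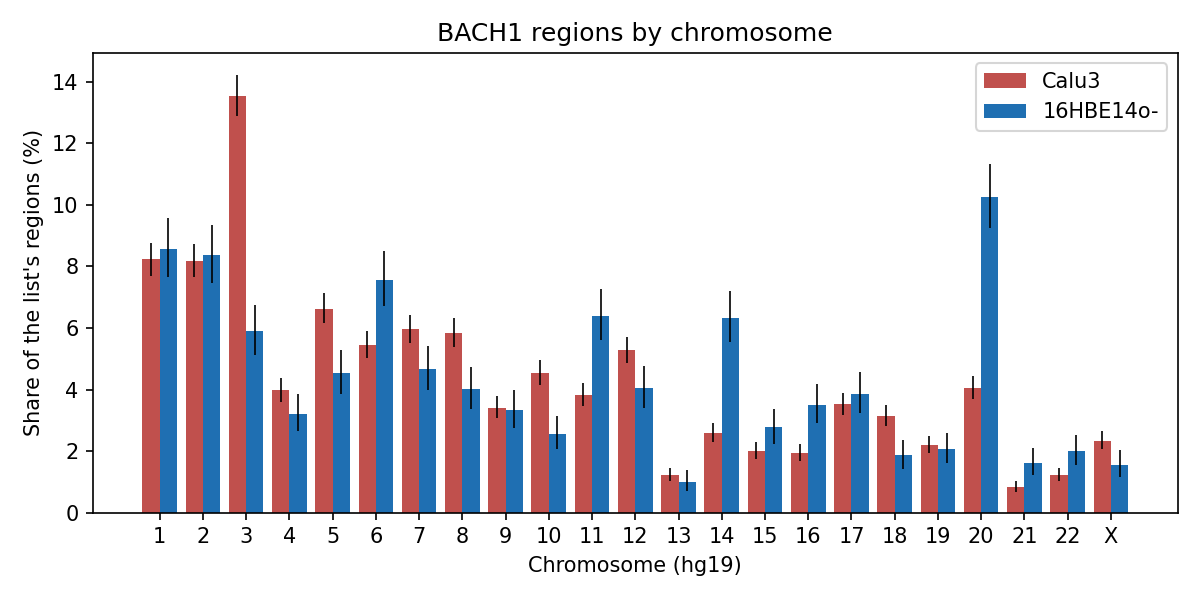
Share of each list's regions (y axis, percent) on chromosomes 1 to 22 and X (x axis) in Calu3 (red) and 16HBE14o- (blue), with 95% exact binomial intervals. Chromosome 3 stands out in Calu3 at 13.5% and chromosome 20 in 16HBE14o- at 10.3%.

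**Figure D4:**
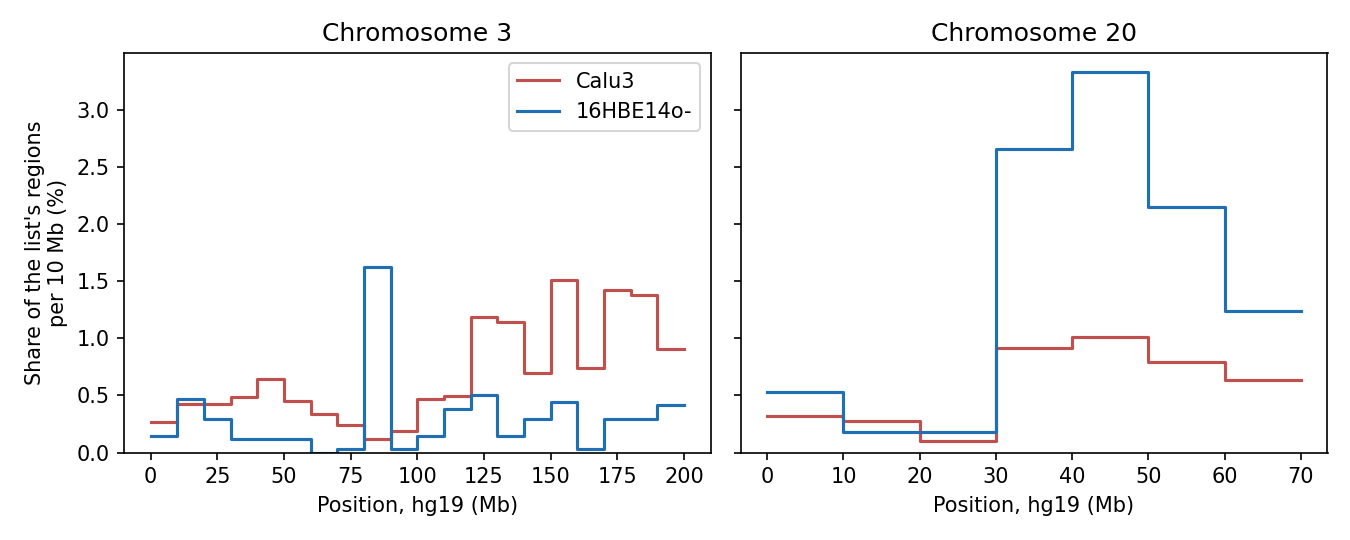
Share of each list's regions per 10 Mb (y axis, percent) along chromosomes 3 and 20 (x axis, hg19 position in Mb) in Calu3 (red) and 16HBE14o- (blue). On chromosome 3, Calu3 holds 337 regions from 0 to 80 Mb and 1039 from 90 Mb onwards, and between them 12 against 55 of 16HBE14o-; on chromosome 20, 16HBE14o- holds 318 regions from 30 Mb onwards.

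BACH1 regions lay close together more often than evenly placed regions would. In Calu3, 656 windows of 100 kb held 3 or more regions, against a mean of 214 and a maximum of 266 over 1000 placements. In 16HBE14o- 161 windows did, against a mean of 19.8 and a maximum of 36 (one-sided permutation p by placement = 0.001 in both lines, the smallest that 1000 placements can give). These windows held 23.6% of the Calu3 regions (95% interval 22.7 to 24.4) and 17.5% of the 16HBE14o- regions (95% interval 16.2 to 18.8), and 54 windows were in both sets. Even placement takes no account of genes, open chromatin or copy number. Without the Calu3 regions with a q of 0.05 or more, 335 Calu3 windows remained, against a mean of 79.9 over the placements of that shorter list.

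The windows with most Calu3 regions were on chromosome 18, where 30 regions lay from 75900001 to 76000000 and 25 from 75800001 to 75900000, with none of 16HBE14o- in either. Of these 55 regions, 47 had a q of 0.05 or more, and their median fold enrichment was 2.51. Next came chromosome 3 from 149000001 to 149100000 with 10 regions, then chromosome 3 from 193500001 to 193600000 and chromosome 20 from 30100001 to 30200000 with 9 each, where 16HBE14o- had 3, 1 and 6. In 16HBE14o- the window with most regions was chromosome 11 from 65600001 to 65700000, with 10 regions against 4 in Calu3. Chromosome 20 from 49300001 to 49400000 held 9 against 3 in Calu3, and chromosome 3 from 87000001 to 87100000 held 8 against 0. Chromosome 20 from 43900001 to 44000000 and from 60900001 to 61000000 held 7 each, against 2 and 5 in Calu3.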

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

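The overlap exceeded that of shifted lists (permutation p = 0.001) under all 10 alternatives run, of which 2 were chosen after seeing the data (Calu3 without regions of q 0.05 or more, or without its 2 densest windows). Across them the shared share of 16HBE14o- regions ran from 31.1% with equal list sizes to 57.7% in the upper 50% of each list, and that of Calu3 from 12.6% with reciprocal overlap to 44.0% in the 500 strongest regions of each list. The percentile differences between shared and unshared regions kept their direction and significance under the 4 alternatives run in each line, from 34.0 to 50.7 points; 2 of the 4, a fixed width of 200 bp and Calu3 without regions of q 0.05 or more, were chosen after seeing the data. By construction, keeping rows at or above the median of column 9 left 5135 Calu3 regions over 1.64 Mb and 1706 regions of 16HBE14o- over 0.403 Mb. The chromosomes that differed fell from 16 to 9 in the upper 50% of each list. Fewer regions were tested there, and on the chromosomes that lost their call the differences were also smaller, except on chromosome 12. The number was 15 without Calu3 regions of q 0.05 or more and 12 without the dense windows, both chosen after seeing the data. Among the 9, 15 and 12 chromosomes, respectively, 8, 14 and 11 belonged to the 16, and the remaining chromosome each time was 4. Windows of 50 kb with 3 or more regions numbered 354 in Calu3 and 91 in 16HBE14o-, and 335 Calu3 windows of 100 kb were left without regions of q 0.05 or more; each still exceeded the placements (permutation p = 0.001). No called difference reversed. No paired analysis was possible because each line was deposited as 1 list pooled over its replicates, so neither a replicate block nor leaving out a replicate could be run. Other settings foreseen for peak annotation, gene lists and motifs were not run. Read depth is unknown, so a region in only 1 list was not detected in the other at an unknown depth and is not shown to be absent.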

Other observations

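The setting without dense windows, the comparison of the upper 50% of the lists as a test of cause, the widths of regions lost under reciprocal overlap and the distances on chromosome 18 were chosen after seeing the data. The strongest sites without a counterpart and the stretches of 10 Mb on chromosomes 3 and 11 were also chosen after their values were seen, and the intervals of these stretches take no account of that choice. In Calu3 the strongest region with no 16HBE14o- region overlapping it or within 500 bp of its summit lay on chromosome 5 from 137937095 to 137937700, with a fold enrichment of 34.2 and rank 22. It was followed by chromosome 8 from 132828332 to 132829023 (fold enrichment 28.7, rank 51) and chromosome 2 from 212008838 to 212009193 (fold enrichment 28.7, rank 52). In 16HBE14o- the strongest such regions lay on chromosome 20 from 24015691 to 24015786 (signal 153, rank 42) and from 36825015 to 36825254 (signal 135, rank 63). The next were chromosome 19 from 47562060 to 47562299 (signal 122, rank 78) and again chromosome 20, from 50720085 to 50720324 (signal 120, rank 80). Of the 500 strongest regions, 177 in Calu3 and 47 in 16HBE14o- met no region of the other list.

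Within 80 to 90 Mb of chromosome 3, 16HBE14o- held 55 regions (1.62% of its list, 95% interval 1.22 to 2.10), against 12 in Calu3 (0.117%, 95% interval 0.061 to 0.204). None of the 55 was shared, and their median within-list percentile of signal was 25.4. Within 60 to 70 Mb of chromosome 11, 16HBE14o- held 104 regions (3.07%, 95% interval 2.51 to 3.70) and Calu3 held 74 (0.722%, 95% interval 0.568 to 0.906). Of the Calu3 regions with a q of 0.05 or more, 3.77% (95% interval 3.09 to 4.56) were shared, against 19.5% (95% interval 18.7 to 20.5) of those with a lower q.

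The excess of regions on chromosome 3 in Calu3 and on chromosome 20 in 16HBE14o- was weighed against technical explanations. A few dense clusters are argued against as the whole cause. Without windows of 3 or more regions, chromosome 3 still held 10.5% of the Calu3 list (95% interval 9.85 to 11.2). Chromosome 20 still held 7.11% of the 16HBE14o- list (95% interval 6.18 to 8.12). Each was above the interval of the other list with its dense windows kept (5.13 to 6.74 for chromosome 3 and 3.68 to 4.45 for chromosome 20). With those windows left out of both lists, the other list held 5.50% and 3.19%, respectively. Extra weak peaks may contribute, since chromosome 3 held 17.2% of the lower 50% of the Calu3 list (95% interval 16.2 to 18.3) and 9.88% of the upper, and chromosome 20 held 12.4% of the lower 50% of the 16HBE14o- list (95% interval 10.8 to 14.04) and 8.14% of the upper. The upper 50% alone still exceeded that of the other line, where the shares were 4.83% (95% interval 3.86 to 5.97) for chromosome 3 and 2.65% (95% interval 2.23 to 3.13) for chromosome 20. Peaks of the lower 50% were therefore not the whole of the excess. This does not weigh against extra weak peaks in general, since the upper 50% of the Calu3 list begins at its median fold enrichment of 4.13. Additional copies of these chromosomes, or of parts of them, in 1 line are a candidate explanation that, like a difference in binding between the lines, was not tested directly, as no input library was analysed here.

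For the 1814 regions of 16HBE14o- with no Calu3 region, small shifts in where peaks were placed are argued against, since counting summits within 500 bp raised the shared share by only 0.53 percentage points, to 47.1%. Weak peaks near the end of the list are consistent with the pattern: 93.2% of the strongest decile were shared, against 15.0% of the weakest. With a reciprocal overlap of 50% the strongest decile fell to 54.3% (95% interval 48.8 to 59.7), below the limit set for excluding this explanation. That limit does not apply to this rule, since the counterparts of all 132 regions lost were over 2 times as wide, which rules out such an overlap. With summits within 100 bp the share was 91.7%. The share also changed with the length of the lists. For the strongest decile of the 16HBE14o- regions kept, it was 87.6% with equal list sizes and 82.0% with the 500 strongest regions of each list. Both are under the share set in advance as fitting this explanation. In the upper 50% of each list it was 97.1%. Whether the weak regions are bound only in 16HBE14o-, lie under the threshold in Calu3 or are not bound in either was not tested, and the cell line remains an open, untested difference.

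The 55 Calu3 regions from 75.8 to 76.0 Mb of chromosome 18 were weak. Their median within-list percentile of signal was 6.71 (95% interval 4.57 to 10.2), and the best of them ranked 7511 of 10246. They may be extra weak peaks, as more copies of the segment would give, which was not tested directly. The 200 kb before this block held 10 regions and the 200 kb after it 3. The block was picked as the 2 densest Calu3 windows, so lower counts on either side follow from that choice. They cannot weigh for or against a lower threshold, which was not tested directly either. A single broad enrichment called in pieces cannot be told apart for these regions, because the median distance between neighbouring summits was 2587 bp, with an interval of 1702 to 3296 bp that lies above 1 kb but reaches below the 2 kb set as the limit for excluding it. No biological explanation was tested.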
